A study of Homo sapiens with 6 samples.

How the data were processed

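RNA was sequenced from A549 cells, an established human lung adenocarcinoma line, in 6 libraries. Per the labels, 3 libraries came from cells overexpressing wild-type KAT8 (WT) and 3 from cells overexpressing the R98W form of KAT8, an amino acid substitution, and the RNA was polyadenylated RNA from a column-based total RNA extraction. Groups and replicate numbers were taken from the sample titles. No library from cells without overexpression was used here. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

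The deposited table held raw read counts per gene, as whole numbers with no normalisation, in 1 column per library. The submitters' processing notes name CASAVA 1.8, HISAT2 2.1.0, HTSeq 0.11.3 and the human genome build hg38, without the role of each. The gene annotation, the strand setting and the read filters of the counting are not given in the sources used here. Reads from a gene and from an overlapping gene on the opposite strand therefore cannot be told apart, and genes with near-identical copies are uncertain. All 58721 rows of the table matched a gene of GENCODE release 29 by identifier, which gave biotypes, symbols and positions on hg38. Overlaps are given between annotated genes that were both tested.

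Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default minimum count of 10 and minimum total count of 15, which left 20713 genes. Libraries were scaled by TMM, and the quasi-likelihood test (glmQLFit and glmQLFTest) compared R98W with WT in a fit of all 6 libraries without covariates. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05, and a gene past it is called higher or lower. Fold changes are log2 of R98W over WT, with the standard error (SE) taken from the test statistic. Expression levels are CPM computed from the TMM-scaled library totals and given as mean ± SD over the 3 libraries of a group.

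Named genes followed a rule: KAT8, the 12 largest rises and the 12 largest falls among called protein-coding genes with a mean of at least 1 CPM and no overlap between the groups, the 5 rises and the 5 falls with the smallest p, and the 4 members of each gene list with the smallest p. Of the named members that were not called, only MSL2, MSL3, PDGFRL and CD14 are given. In the closing part, genes of some symbol stems were added. Some genes that the rule names are not reported here. The 33 gene lists, the test, the naming rule and most alternatives were fixed before the data were examined. The lists were written from textbook knowledge, and 3 of their 698 entries were not found by symbol. Lists with at least 4 tested members were compared with all other genes by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the 33 lists. Camera with an estimated correlation and fry were alternatives. Each list's median was also placed among 10000 random lists matched on mean expression.

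Alternatives were scaling by DESeq2 size factors and by the upper quartile, no filter, a filter of at least 50 counts in 3 libraries, KAT8 left out, each library left out, the replicate number as a block, limma-voom, DESeq2 1.42.0, a threshold of 0.01, a minimum fold of 2 and a test against a fold of 1.2. Per-library loess corrections for GC content, exon length and expression level were chosen after the data were seen, as were a thinning of the counts of each library to 50% and 25%, the grouping of genes by symbol stem and the values without the library labelled WT replicate 1 given beside gene lists.

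The pipeline was tested on simulated data: for R98W against WT, counts were drawn from the real means and library sizes with 50 genes changed at each of 4 fold sizes. Calls recovered 34% of genes at a fold of 1.25, 66% at 1.5, 70% at 2 and 94% at 4, with 7 false calls among the 20019 unchanged genes that passed the filter, of 20212 genes tested, and 0 calls in the wrong direction. The simulated changes were few, and as many went up as down. In the real comparison 34.8% of genes were called and large changes were mostly falls, so these rates may not carry over. All 5 simulated lists raised by a fold of 1.3 were found, with 0 false lists, in a simulation without correlation between genes. Library totals ran from 90007121 to 110152936 counts. The biological coefficient of variation was 10%.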

Results

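The data are gene-level RNA-seq counts from 6 libraries of A549 cells, 3 labelled as overexpressing wild-type KAT8 and 3 labelled as overexpressing KAT8 R98W. KAT8, also called MOF, is the lysine acetyltransferase that acetylates histone H4 within the MSL and NSL complexes, and the series concerns a change in its Tudor-knot domain. The libraries labelled WT replicates 1 to 3 held 97185632, 110152936 and 90007121 counts, and R98W replicates 1 to 3 held 102450786, 101792328 and 108742650. The design makes 1 comparison, R98W against WT, which asks how transcript levels differ when the altered protein takes the place of the wild-type protein as the overexpressed form.

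KAT8 (ENSG00000103510, chromosome 16, 31115754 to 31131393, hg38) was high in 5 libraries and low in 1. It reached 195 CPM in WT replicate 2, 184 CPM in WT replicate 3, and 166, 196 and 236 CPM in R98W replicates 1 to 3. The library labelled WT replicate 1 held 12.2 CPM, from 1214 counts, which was 6.43% of the mean of the other WT libraries. The difference between the groups did not pass the threshold, with a log2 fold change of 0.61 (SE 0.48, edgeR adjusted p = 0.362). Without the library labelled WT replicate 1 the log2 fold change was 0.06 (SE 0.10, edgeR adjusted p = 0.687). Over 16 alternatives the KAT8 log2 fold change ran from 0.06 to 1.37 and its adjusted p from 6.72e-16 to 0.687, past the threshold in 2 of them. KAT8 reads do not separate the introduced from the chromosomal gene, nor WT from R98W sequence, and the gene overlaps AC135050.5 and AC135050.6 on its own strand. All WT values below include the library labelled WT replicate 1, and counts without it are given beside the totals and the gene lists.

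**Figure D1:**
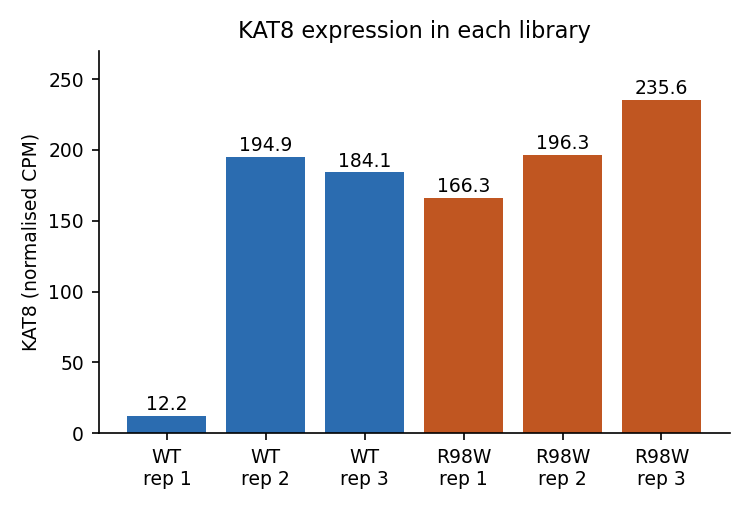
Bars show KAT8 expression in TMM-scaled CPM, 1 bar per library, for the 3 WT and 3 R98W libraries. The library labelled WT replicate 1 stands at 12.2 CPM, and the other libraries lie between 166 and 236 CPM.

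R98W cells differed from WT cells in a large part of the transcriptome. Called genes were mostly higher among abundant transcripts and mostly lower among weakly expressed ones. Of 20713 genes tested, 3364 were higher and 3839 were lower in R98W by edgeR, together 34.8% of the tested genes, and the median absolute log2 fold change of the called genes was 0.44. Without the library labelled WT replicate 1, 3268 were higher and 3944 lower. Higher genes outnumbered lower ones after the corrections for GC content (3898 higher, 3684 lower) and exon length (3953 higher, 3579 lower), both chosen after the data were seen. Changes of at least 2-fold were mostly falls, with 155 genes higher and 1005 lower, and changes of at least 4-fold numbered 17 higher and 236 lower. After a correction for expression level, chosen after the data were seen, the 2-fold counts were 257 higher and 750 lower. Among genes over 64 CPM, 1391 were higher and 324 lower, whereas among genes under 1 CPM 153 were higher and 687 lower. Over all tested genes at these levels the median log2 fold changes were 0.132 and -0.128. Calls took in 49.8% of the tested genes over 64 CPM and 13.1% of those under 1 CPM, where small changes are harder to call. Protein-coding genes made up 2930 of the higher and 3317 of the lower genes. The groups did not overlap in 95.6% of the called genes and in 45.6% of all tested genes, against 10% by chance. The main axis of variation carried 50.6% of the variance and separated the WT from the R98W libraries.

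**Figure D2:**
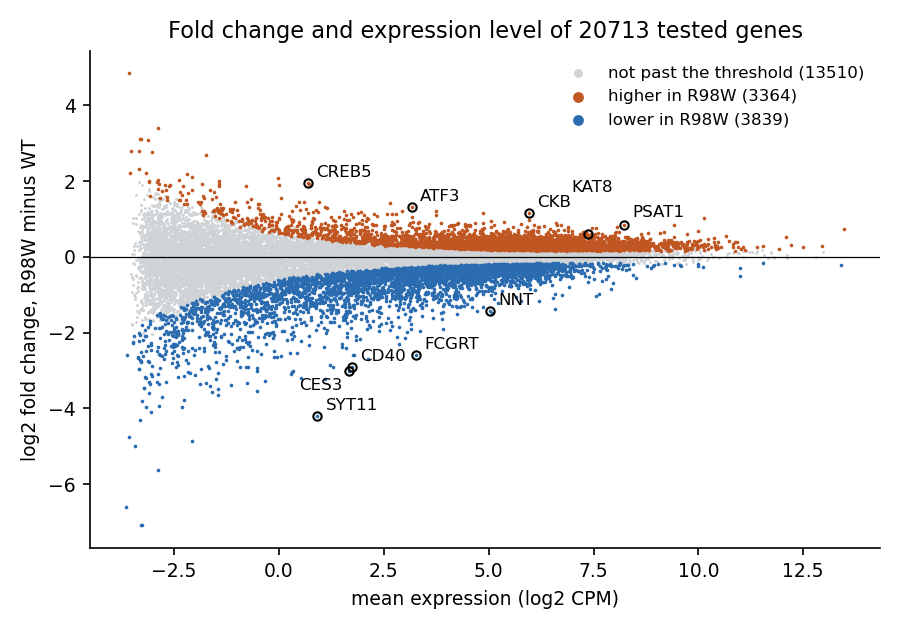
Each point is 1 of 20713 tested genes, with mean expression in log2 CPM on the x axis and the log2 fold change of R98W over WT on the y axis. The 3364 higher and 3839 lower genes are coloured, 10 named genes are circled, and the falls reach further from 0 than the rises among genes of similar expression.

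Among called protein-coding genes with a mean of at least 1 CPM and no overlap between the groups, CREB5 and ADRA2A rose most. CREB5 (ENSG00000146592, chromosome 7, 28299321 to 28825894), a transcription factor that binds cAMP response elements, rose from 0.66 ± 0.16 CPM (SD, n = 3) in WT to 2.54 ± 0.54 CPM in R98W, a log2 fold change of 1.95 (SE 0.23, edgeR adjusted p = 2.39e-06). ADRA2A, an adrenergic receptor, rose by 1.91 on the log2 scale. The chemokine receptor CXCR4 rose by 1.45, the receptor tyrosine kinase RET by 1.27 and the muscarinic receptor CHRM3 by 1.24. The stress-induced transcription factor ATF3 rose from 5.12 ± 0.41 to 12.8 ± 0.85 CPM, a log2 fold change of 1.32. The netrin receptor UNC5B rose from 1.26 ± 0.10 to 3.11 ± 0.08 CPM. HEY1, a Notch target and repressor, rose by 1.31, the extracellular protease ADAMTS1 by 1.56, RGMA by 1.44, NIBAN1 by 1.42 and GCNA by 1.35. All 12 were past the edgeR threshold with and without the library labelled WT replicate 1.

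The largest falls by the same rule left several genes under 1 CPM in R98W. SYT11 (ENSG00000132718, chromosome 1, 155859509 to 155885199), a synaptotagmin of vesicle traffic, fell from 3.53 ± 1.03 CPM to 0.192 ± 0.129 CPM (SD, n = 3), a log2 fold change of -4.20 (SE 0.32, edgeR adjusted p = 1.64e-08). QPRT, an enzyme of NAD synthesis from quinolinate, had a log2 fold change of -3.21, as did CCDC136. The carboxylesterase CES3 fell from 5.65 ± 1.11 to 0.702 ± 0.129 CPM, and the tumour necrosis factor receptor family member CD40 fell from 5.82 ± 0.87 to 0.77 ± 0.13 CPM. Log2 fold changes were -3.04 for PLEKHB1, -3.02 for the microtubule-associated MAP6, -2.90 for FSD1, -2.86 for FAM229B and -2.70 for DMKN. MDH1B had -3.10 and overlaps FASTKD2 on the other strand. Each of the falls named here also passed the edgeR threshold without the library labelled WT replicate 1.

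**Figure D3:**
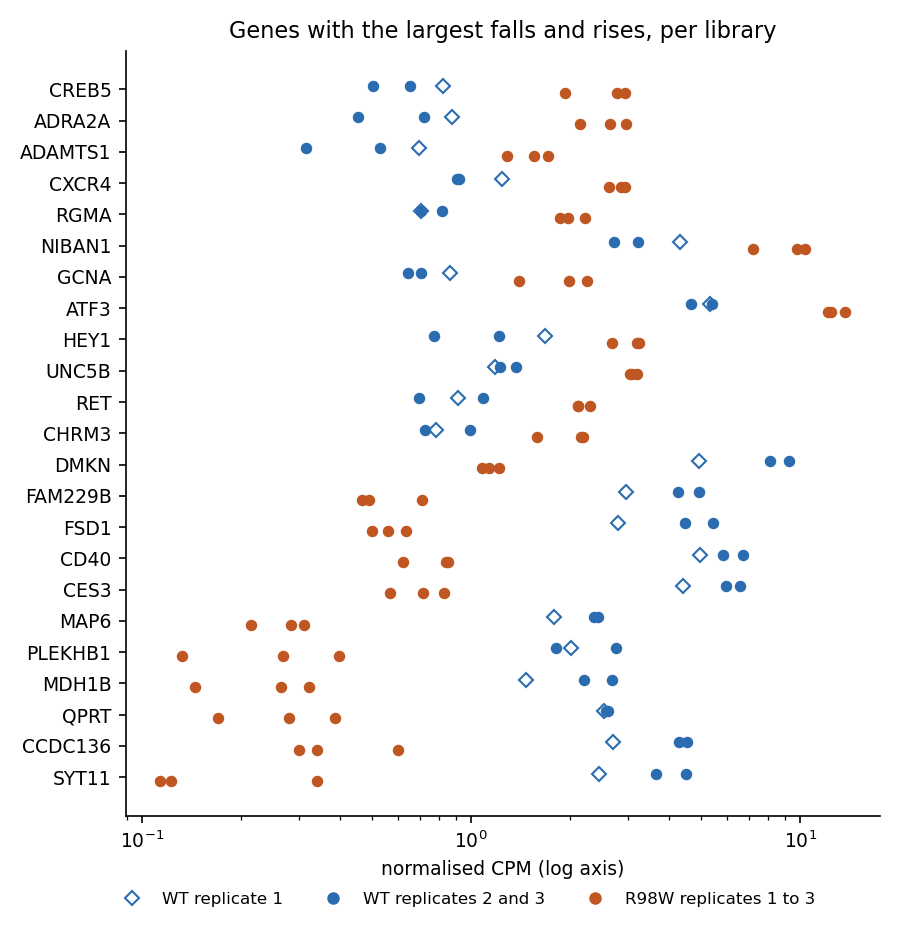
Points show TMM-scaled CPM on a log axis for the genes named above for the largest rises and falls, 1 point per library, with R98W libraries in orange and WT libraries in blue. Open diamonds mark the library labelled WT replicate 1. It lies on the WT side for every gene shown because the rule that chose these genes required no overlap between the groups.

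The changes with the smallest p-values were in more abundant transcripts. FCGRT (ENSG00000104870, chromosome 19, 49506816 to 49526333), the heavy chain of the neonatal Fc receptor, fell from 16.5 ± 0.80 to 2.74 ± 0.19 CPM (SD, n = 3), a log2 fold change of -2.59 (SE 0.11, edgeR adjusted p = 1.74e-11). The mitochondrial transhydrogenase NNT fell from 47.8 ± 1.4 to 17.8 ± 0.64 CPM, and it overlaps NNT-AS1 and RPL29P12 on the other strand. EHD3, an endosomal recycling protein, had a log2 fold change of -1.90, TCTN2, a protein of the ciliary transition zone, had -2.31, and the glutaminyl cyclase QPCT had -1.48. Among the rises, the brain-type creatine kinase CKB went from 38.7 ± 4.9 to 86.2 ± 7.5 CPM, a log2 fold change of 1.16 (SE 0.09, edgeR adjusted p = 1.29e-08). The neurofilament gene NEFL rose from 18.2 ± 2.2 to 40.3 ± 1.3 CPM. PSAT1 of serine synthesis rose by 0.83 on the log2 scale, the galectin gene LGALS3 by 0.79 and the histone gene H2BC12 by 0.93.

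Of the 33 gene lists, 13 passed the camera threshold, 10 toward R98W and 3 toward WT. With an estimated inter-gene correlation camera called 0 of the 33, with adjusted p from 0.122 to 0.815 and 6 lists at an unadjusted p under 0.05. Fry called 17, among them 12 of the 13. Unlike camera, fry does not compare a list with other genes, of which 34.8% were called over all tested genes, so it answers another question. The medians of 9 of the 13 lay outside the 95% range of expression-matched random lists, and those of the heat shock, MYC, NRF2 and mitochondrial DNA lists lay inside it.

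Targets of p53 rose together, with 24 of 26 members higher and 0 lower, and the same counts adjusted over the list alone. The median log2 fold change was 0.49 (camera adjusted p = 1.35e-10, and adjusted p = 0.341 with an estimated correlation). The translesion polymerase POLH rose from 31.3 ± 1.9 to 49.8 ± 1.5 CPM, SESN1 rose by 0.70 on the log2 scale, the cyclin CCNG1 by 0.63 and FDXR by 0.79. POLH overlaps GTPBP2 and POLH-AS1 on the other strand. Leaving out the library labelled WT replicate 1 gave 25 higher members. Genes of the ATF4 integrated stress response rose in 14 of 21 cases with 0 lower, or 17 and 0 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 4.82e-07, and adjusted p = 0.338 with an estimated correlation). The serine and folate pathway enzymes led this list. PSAT1 rose from 217 ± 9.4 to 386 ± 20 CPM, MTHFD2 from 142 ± 9.9 to 238 ± 5.4 CPM, PSPH from 57.9 ± 4.2 to 102 ± 6.7 CPM and PHGDH from 27.8 ± 0.76 to 44.2 ± 3.8 CPM. MTHFD2 overlaps SLC4A5 on the other strand. The ATF4 list had 15 higher members without the library labelled WT replicate 1.

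Cholesterol and fatty acid synthesis genes were higher in 24 of 28 cases and lower in 0, or 27 and 0 adjusted over the list alone, with a median log2 fold change of 0.38 (camera adjusted p = 1.35e-10, and adjusted p = 0.237 with an estimated correlation). The isomerase IDI1 rose from 87.2 ± 6.4 to 149 ± 1.9 CPM (SD, n = 3). The sterol carrier STARD4 rose by 0.72 on the log2 scale and MSMO1 by 0.70. STARD4 overlaps STARD4-AS1 on the other strand. With the library labelled WT replicate 1 left out, 25 members were higher and 0 lower.

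The ribosomal protein, heat shock, MYC and NRF2 lists passed the camera threshold toward R98W with smaller medians. Cytosolic ribosomal protein genes were higher in 24 of 27 cases, or 26 adjusted over the list alone, and lower in 0, with a median of 0.30 (camera adjusted p = 1.33e-07, and adjusted p = 0.436 with an estimated correlation). RPS2 rose by 0.47, RPL5 by 0.42, RPLP0 by 0.40 and RPL7 by 0.37 on the log2 scale. These genes have many processed pseudogenes, so the split of reads between them is uncertain. Processed pseudogenes of all parent genes together were higher in 228 and lower in 35 of 1993 cases. Cytosolic heat shock genes were higher in 12 of 15 cases, or 13 adjusted over the list alone, and lower in 0, with a median of 0.25 (camera adjusted p = 3.76e-05, and adjusted p = 0.237 with an estimated correlation). The cochaperone BAG3 rose by 0.48, HSPA1B by 0.40, HSPH1 by 0.35 and HSPE1 by 0.32. HSPA1B has a near-identical copy, and HSPE1 overlaps HSPD1 on the other strand. MYC and nucleolar targets were higher in 10 and lower in 2 of 25 cases, or 11 and 2 adjusted over the list alone, with a median of 0.17 (camera adjusted p = 0.00322, and adjusted p = 0.35 with an estimated correlation). GNL3 rose by 0.46, NOP56 by 0.42, NOP58 by 0.40 and TFRC by 0.35. NRF2 targets were higher in 11 and lower in 1 of 25 cases, the same adjusted over the list alone, with a median of 0.15 (camera adjusted p = 0.00322, and adjusted p = 0.35 with an estimated correlation). GCLM of glutathione synthesis rose by 0.41, TXN by 0.30, and TXNRD1 and AKR1B10 each by 0.29. After the correction for expression level the calls of TXN, TXNRD1 and AKR1B10 ended, with log2 fold changes of 0.11, 0.05 and 0.03 and edgeR adjusted p of 0.228, 0.503 and 0.664, and TXN also stood at 0.0934 after the correction for GC content. After the correction for expression level the ribosomal protein list stayed past the camera threshold, at 0.0306, with RPS2 at 0.26, RPL5 at 0.22, RPLP0 at 0.18 and RPL7 at 0.20. The heat shock, MYC and NRF2 calls ended after the correction for expression level, with camera adjusted p of 0.251, 0.382 and 0.527, the last with the direction turned. Over the camera alternatives adjusted p ran from 1.01e-05 to 0.251 for heat shock, from 0.000329 to 0.382 for MYC and from 0.00111 to 0.527 for NRF2. The higher members without the library labelled WT replicate 1 were 19 for ribosomal proteins, 12 for heat shock, 11 for MYC and 13 for NRF2.

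DNA replication and recombination genes moved toward lower levels in R98W. S phase and DNA replication genes were lower in 20 of 27 cases and higher in 1, or 21 and 1 adjusted over the list alone, with a median log2 fold change of -0.34 (camera adjusted p = 2.65e-06, and adjusted p = 0.122 with an estimated correlation). MCM5, a subunit of the replicative helicase, fell from 95.5 ± 0.64 to 60.7 ± 3.3 CPM and MCM7 from 220 ± 8.4 to 148 ± 6.9 CPM (SD, n = 3). UHRF1, which maintains DNA methylation, had a log2 fold change of -0.68 and MCM2 -0.52. MCM7 overlaps AP4M1, and MCM2 overlaps TPRA1, on the other strand. Homologous recombination and Fanconi genes were lower in 13 of 23 cases and higher in 0, or 16 lower and 1 higher adjusted over the list alone, with a median of -0.30 (camera adjusted p = 0.000247, and adjusted p = 0.338 with an estimated correlation). RAD51B fell from 5.86 ± 0.84 to 2.64 ± 0.17 CPM, and FANCD2 had -0.62, BLM -0.58 and EXO1 -0.47 on the log2 scale. Genes of G2 and mitosis did not pass the camera threshold, with 3 higher and 2 lower of 26, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.653). After the correction for expression level this list passed toward WT, at a camera adjusted p of 0.0306, and its median log2 fold change of -0.0469 lay under the 95% range of expression-matched lists, 0.00196 to 0.205. HMMR and KIF20A were higher, while MKI67 and TOP2A were lower, with log2 fold changes of -0.29 and -0.20. The KIF20A call ended without WT replicate 3 or R98W replicate 2, at edgeR adjusted p of 0.128 and 0.0722, and after the correction for expression level, at 0.0825, and the TOP2A call without R98W replicate 2 or 3, at 0.0552 and 0.0964. In the fit without the library labelled WT replicate 1, 19 S phase genes and 15 recombination genes were lower and 0 were higher in either list, and 2 G2 genes were higher and 2 lower.

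Replication-dependent histone genes rose, with 9 of 13 tested members higher and 0 lower, the same adjusted over the list alone, and a median log2 fold change of 0.49 (camera adjusted p = 1.16e-05, and adjusted p = 0.122 with an estimated correlation). H2BC12 and H1-2 rose by 0.93 and 0.83 on the log2 scale, to 44.0 ± 1.3 and 44.4 ± 2.4 CPM. H4C8 rose from 5.83 ± 0.26 to 12.1 ± 0.56 CPM and H2BC4 from 3.01 ± 0.19 to 6.64 ± 0.06 CPM (SD, n = 3). Near-identical copies make single histone genes uncertain. These mRNAs mostly end in a stem-loop and not a poly(A) tail. The share of counts from mitochondrial ribosomal RNA was higher in the same libraries, at 1.47%, 1.57% and 1.48% in R98W replicates 1 to 3 against 1.04%, 0.905% and 0.937% in WT replicates 1 to 3. The count of 9 higher histone genes was the same without the library labelled WT replicate 1.

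Interferon genes moved down and immediate early genes moved up. Type I interferon response genes were lower in 9 and higher in 2 of 21 cases, the same adjusted over the list alone, with a median log2 fold change of -0.34 (camera adjusted p = 0.021, and adjusted p = 0.237 with an estimated correlation). PARP9 fell from 23.9 ± 0.79 to 13.3 ± 1.1 CPM and the RNA sensor IFIH1 from 5.50 ± 0.14 to 2.48 ± 0.12 CPM (SD, n = 3). IFI6 had a log2 fold change of -1.50 and OAS3 -0.44. PARP9 overlaps DTX3L on the other strand. Immediate early genes were higher in 10 and lower in 2 of 21 cases, or 11 and 2 adjusted over the list alone, with a median of 0.23 (camera adjusted p = 0.00456, and adjusted p = 0.237 with an estimated correlation). ATF3 led the rises, FOSL1 rose by 0.59, and JUNB had -0.53 and overlaps HOOK2 on the other strand. EGR2 stood at 0.126 ± 0.012 CPM in R98W and 0.0029 ± 0.0050 CPM in WT, too low for a fold change. NF-kB and inflammatory cytokine genes went both ways, with 7 higher and 2 lower of 21, the same adjusted over the list alone (camera adjusted p = 0.295). NFKB2 rose by 0.65, BIRC3 by 0.58 and CXCL5 by 0.52, whereas the complement gene C3, which overlaps GPR108 on its own strand, fell from 101 ± 9.9 to 45.3 ± 4.6 CPM. In the fit without the library labelled WT replicate 1, 9 interferon genes were lower and 2 higher, 9 immediate early genes were higher and 3 lower, and 8 NF-kB genes were higher and 2 lower.

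**Figure D4:**
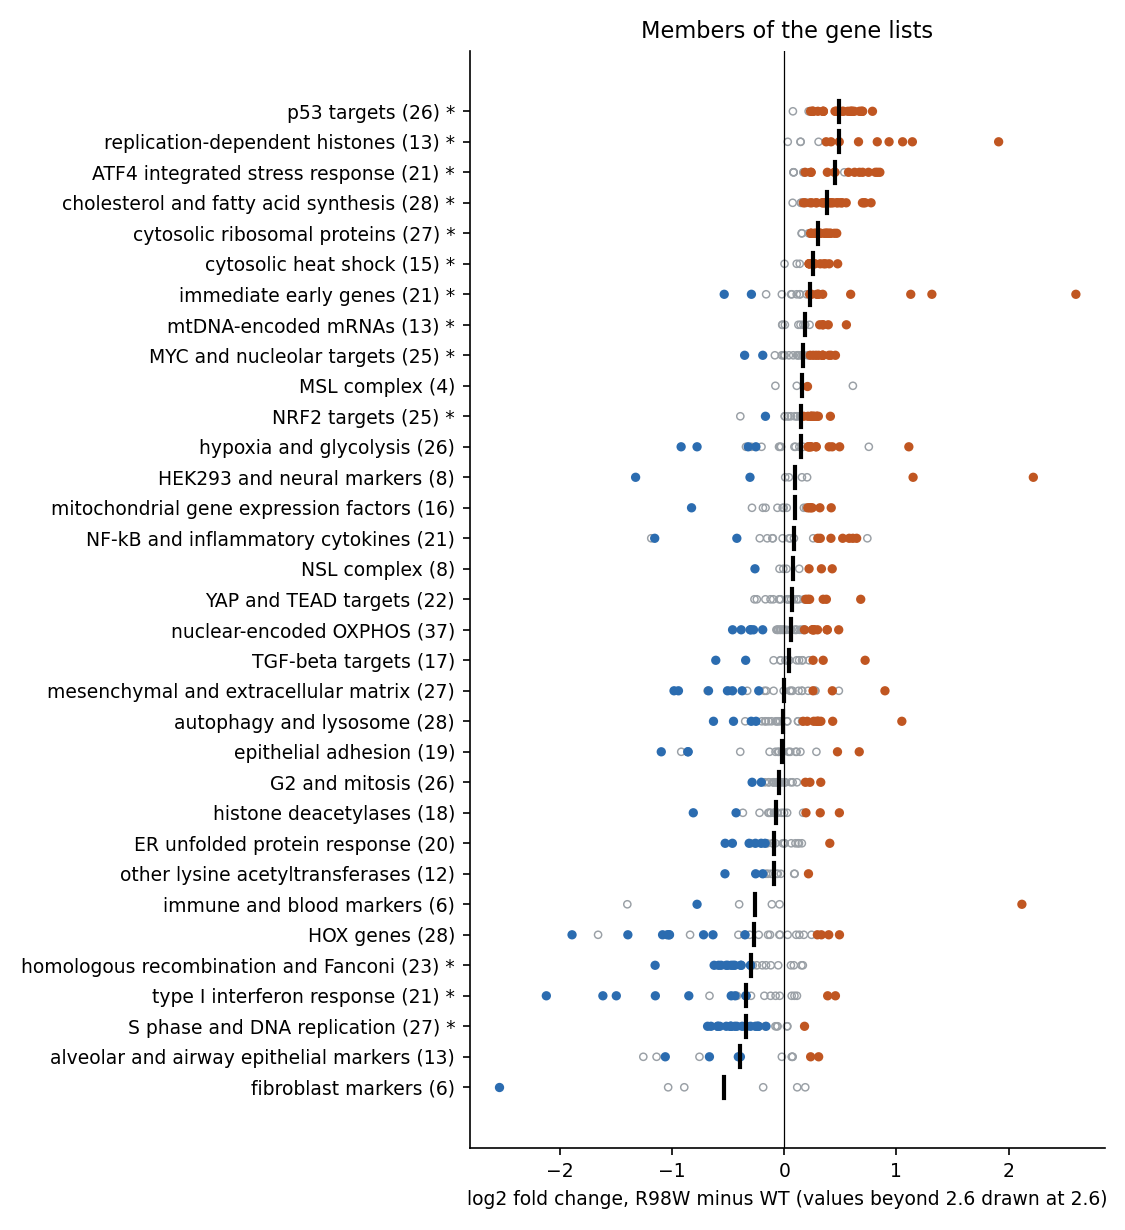
Each row is a gene list with its number of tested members, each point a member's log2 fold change of R98W over WT, filled where the gene was called, and the black bar the list's median. Asterisks mark the 13 lists past the camera threshold, whose medians run from -0.34 for S phase to 0.49 for p53 targets.

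None of the lists of KAT8 complexes and related enzymes passed the camera threshold, while single members changed, among them OGT and HDAC11. Of the 8 NSL complex genes 3 were higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.305). The glycosyltransferase OGT rose from 135 ± 2.8 to 182 ± 8.4 CPM, KANSL2 rose by 0.33 and KANSL1 by 0.22 on the log2 scale, and MCRS1 had -0.26. The KANSL1 call ended without WT replicate 2, WT replicate 3 or R98W replicate 2, at edgeR adjusted p of 0.0963, 0.131 and 0.133, and the MCRS1 call without R98W replicate 2, at 0.0624. Of the 4 MSL complex genes, KAT8 included, only MSL1 was called, with a log2 fold change of 0.20 and the same count adjusted over the list alone (camera adjusted p = 0.41). That call ended without WT replicate 2, WT replicate 3, R98W replicate 1 or R98W replicate 2, at edgeR adjusted p of 0.0811, 0.0939, 0.0949 and 0.0737. MSL2 had 0.11 and MSL3 had -0.08, neither past the threshold. Of 12 other lysine acetyltransferase genes, 1 was higher and 3 were lower, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.368), with ATAT1 at -0.53, KAT5 at -0.25, HAT1 at -0.19 and KAT2B at 0.22. With the library labelled WT replicate 1 left out, KAT5 stood at an edgeR adjusted p of 0.088 and KAT2B at 0.0797. Other single libraries also ended these calls: KAT5 stood at 0.0578, 0.13 and 0.106 without WT replicate 2, R98W replicate 1 and R98W replicate 3. KAT2B stood at 0.16, 0.0594, 0.113 and 0.199 without WT replicates 2 and 3 and R98W replicates 1 and 2, each left out alone. HAT1 stood at 0.0864, 0.1, 0.0966, 0.0768 and 0.108 without each of the libraries other than the one labelled WT replicate 1. Of 18 histone deacetylase and sirtuin genes 3 were higher and 2 lower, the same adjusted over the list alone (camera adjusted p = 0.57, and a fry adjusted p of 0.0282 toward WT). HDAC11 fell from 9.08 ± 0.25 to 5.18 ± 0.24 CPM, HDAC8 had -0.43, and SIRT7 and HDAC2 had 0.32 and 0.19. The HDAC2 call ended without the library labelled WT replicate 1, WT replicate 3, R98W replicate 1 or R98W replicate 2, at edgeR adjusted p of 0.0555, 0.0503, 0.104 and 0.0818, and the SIRT7 call without WT replicate 3 or R98W replicate 3, at 0.0689 and 0.0791. The correction for expression level ended the calls of KANSL1, MSL1, KAT5 and HDAC2, at edgeR adjusted p of 0.101, 0.212, 0.174 and 0.374, with log2 fold changes of 0.16, 0.11, -0.17 and 0.08. The fit without the library labelled WT replicate 1 gave 3 higher and 1 lower for NSL, 1 and 0 for MSL, 0 and 2 for the other acetyltransferases and 1 and 3 for the deacetylases and sirtuins.

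Mitochondrial and lysosomal gene groups were mixed. The 13 protein-coding mRNAs of mitochondrial DNA were higher in 5 cases and lower in 0, the same adjusted over the list alone, with a median log2 fold change of 0.19 (camera adjusted p = 0.0369, and adjusted p = 0.663 with an estimated correlation). MT-ND2 rose by 0.55, MT-ND3 by 0.39, MT-ND4L, which overlaps MT-ND4, by 0.35 and MT-ND1 by 0.34. The MT-ND1 call ended without R98W replicate 2, at an edgeR adjusted p of 0.0555, and after the correction for expression level MT-ND1 had 0.12 and MT-ND4L 0.15, at 0.291 and 0.0878. The list call was held in 7 of 15 camera alternatives, with adjusted p from 0.00348 to 0.862, and it ended when WT replicate 2, WT replicate 3 or R98W replicate 2 was left out, at 0.101, 0.0741 and 0.174. It also ended with a filter of at least 50 counts (0.0602), with the replicate block (0.0564), after the corrections for GC content (0.094) and exon length (0.189) and by fry (0.188), and after the correction for expression level its direction turned toward WT, at 0.862. Without the library labelled WT replicate 1, 8 were higher and 0 lower, with a median of 0.297. Nuclear-encoded oxidative phosphorylation genes were higher in 9 and lower in 6 of 37 cases, the same adjusted over the list alone (camera adjusted p = 0.284). CYC1 and ATP5F1B were higher, with log2 fold changes of 0.49 and 0.38, and NDUFV1 and NDUFA10 were lower, with -0.46 and -0.38. This list passed the camera threshold only without WT replicate 2, at an adjusted p of 0.00522, within a range of 0.00522 to 0.933. Mitochondrial gene expression factors were higher in 6 and lower in 1 of 16 cases, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.368), with MRPL11 at -0.83, MRPS12 at 0.42, LRPPRC at 0.32 and POLG at 0.25. The LRPPRC call ended after the correction for expression level, at an edgeR adjusted p of 0.0962. Autophagy and lysosome genes were higher in 9 and lower in 4 of 28 cases, or 9 and 7 adjusted over the list alone (camera adjusted p = 0.653). ATG14 fell from 22.3 ± 1.3 to 14.4 ± 0.09 CPM, while ATG12 rose by 0.43 and MAP1LC3B by 0.33. GABARAP had a log2 fold change of 1.05 at a low level, from 1.74 ± 0.36 to 3.59 ± 0.03 CPM, and overlaps AC120057.3 on the other strand. When the library labelled WT replicate 1 was left out, 6 were higher and 6 lower for oxidative phosphorylation, 5 and 3 for the mitochondrial expression factors and 9 and 4 for autophagy and lysosome.

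The other signalling and metabolic lists did not pass the camera threshold in the main setting, and 3 of the 4 did in another. Hypoxia and glycolysis genes were higher in 11 and lower in 4 of 26 cases, or 12 and 5 adjusted over the list alone (camera adjusted p = 0.102, 0.0422 toward R98W after the correction for GC content, and a fry adjusted p of 0.00506), with ANGPTL4 at 1.11, ALDOA at 0.49, EGLN3 at 0.43 and P4HA1 at 0.40 on the log2 scale. YAP and TEAD targets were higher in 6 and lower in 0 of 22 cases, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.16, and 0.0422 toward R98W after the correction for GC content), led by NT5E at 0.68, MYOF at 0.38, TGFB2 at 0.35 and AMOTL1 at 0.23. The AMOTL1 call ended without WT replicate 3 or R98W replicate 1, at edgeR adjusted p of 0.115 and 0.112, and after the correction for expression level, at 0.142. Genes of the endoplasmic reticulum unfolded protein response were lower in 6 and higher in 1 of 20 cases, the same adjusted over the list alone (camera adjusted p = 0.39, and 0.0112 toward WT after the correction for expression level). Their median of -0.0885 lay under the 95% range of expression-matched lists, -0.0121 to 0.227. DNAJB11 had -0.53, CRELD2 -0.46, SEL1L -0.31 and DNAJB9 0.41. TGF-beta targets were higher in 3 and lower in 2 of 17 cases, the same adjusted over the list alone (camera adjusted p = 0.368), with LTBP2 at -0.61, ID3 at -0.34 and TAGLN at 0.72. Higher and lower members without the library labelled WT replicate 1 numbered 9 and 5 for hypoxia, 8 and 0 for YAP, 1 and 7 for the unfolded protein response and 5 and 2 for TGF-beta.

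None of the HOX, adhesion, matrix and airway lists passed the camera threshold in the main setting. HOX genes were lower in 9 and higher in 4 of 28 cases, the same adjusted over the list alone (camera adjusted p = 0.102). This list passed toward WT without the filter, at a camera adjusted p of 0.047, and by fry, at 0.0148. The neighbouring genes HOXC8, HOXC6 and HOXC4 had log2 fold changes of -1.04, -1.02 and -1.03, and HOXC6 overlaps HOXC8 and HOXC4 on its own strand, while HOXC13 had 0.49. Epithelial adhesion genes were higher in 2 and lower in 3 of 19 cases, the same adjusted over the list alone (camera adjusted p = 0.74). The claudin gene CLDN2 fell from 310 ± 11 to 171 ± 22 CPM and EPCAM had -0.86, whereas CLDN1 had 0.67 and KRT19 0.48. Mesenchymal and extracellular matrix genes were higher in 3 and lower in 7 of 27 cases, the same adjusted over the list alone (camera adjusted p = 0.51), with COL6A1 at -0.98, COL6A2 at -0.94, COL5A1 at -0.67 and VIM at 0.43. Alveolar and airway markers were higher in 2 and lower in 4 of 13 cases, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.362), with a median of -0.39 under the 95% range of expression-matched lists, -0.285 to 0.241. The mucin gene MUC5B fell from 204 ± 55 to 128 ± 21 CPM, ABCA3 had -0.39, NAPSA -1.06 and CAV1 0.31, whose call ended after the correction for expression level, at an edgeR adjusted p of 0.0989. Omitting the library labelled WT replicate 1 gave 4 higher and 10 lower for HOX, 3 and 3 for adhesion, 5 and 8 of 28 for mesenchymal and matrix genes and 2 and 3 for the airway markers.

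None of the 3 marker lists of cell types foreign to the line passed the camera threshold, while fry called the fibroblast and the immune list toward WT, at adjusted p of 0.0342 and 0.0281. Fibroblast markers were lower in 1 and higher in 0 of 6 cases, the same adjusted over the list alone (camera adjusted p = 0.305), and the called gene was THY1, at 2.01 ± 0.37 CPM in WT and 0.341 ± 0.058 CPM in R98W. The fibroblast gene PDGFRL, which overlaps MTUS1 on the other strand, stood at 20.8 ± 2.7 CPM in WT and 18.3 ± 2.4 CPM in R98W, past the edgeR threshold only without the library labelled WT replicate 1, at an adjusted p of 0.0416. Immune and blood markers were higher in 1 and lower in 1 of 6 cases, or 1 and 2 adjusted over the list alone (camera adjusted p = 0.368). HBA1 stood at 0.079 ± 0.032 CPM in WT and 0.35 ± 0.20 CPM in R98W, CD8A at 1.12 ± 0.09 and 0.653 ± 0.024 CPM, and CD14, not past the threshold, at 7.78 ± 0.51 and 7.21 ± 1.32 CPM. The HBA1 call ended without R98W replicate 3 and the CD8A call without WT replicate 2, at edgeR adjusted p of 0.0763 and 0.0505. Markers of HEK293 and neural cells were higher in 2 and lower in 2 of 8 cases, the same adjusted over the list alone (camera adjusted p = 0.51), with NEFL higher, NES at -1.32, CRMP1 at -0.30 and ELAVL3 at 0.11 ± 0.01 CPM in R98W against 0.0225 ± 0.0255 CPM in WT. The CRMP1 and ELAVL3 calls ended without any single library other than the one labelled WT replicate 1, at edgeR adjusted p of 0.0512 to 0.1 for CRMP1 and 0.0965 to 0.166 for ELAVL3. After the correction for expression level CRMP1 stood at 0.162. Fitted without the library labelled WT replicate 1, the fibroblast list had 0 higher and 2 lower of 7, the immune list 1 and 1, and the HEK293 and neural list 2 and 2.

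In flies the KAT8 ortholog serves dosage compensation of the X chromosome, so X-linked genes were compared with autosomal ones. The median log2 fold change of X-linked genes exceeded that of autosomal genes by 0.0081, and by -0.0235 among genes with a mean of at least 5 CPM. Autosome medians ran from -0.0935 on chromosome 19 to 0.0701 on chromosome 4, with an SD of 0.0395, so the X chromosome lay within the spread of the autosomes.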

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

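The corrections for GC content, exon length and expression level and the thinning of counts were chosen after the data were seen. With each library left out in turn, the higher genes numbered 2340 to 3268, the lower genes 3060 to 3944, the called lists 12 to 13, and the KAT8 log2 fold change ran from 0.0627 (without the library labelled WT replicate 1) to 1.011 (without WT replicate 2). Of 160 named genes besides KAT8, 153 were past the threshold, and all 153 kept their sign in every such fit. This says little, since a gene whose groups do not overlap keeps its sign whichever library is left out. No called named gene reversed under any scaling, filter, test or correction, but 14 lost their call under the correction for expression level, TXNRD1 (edgeR adjusted p = 0.503), AKR1B10 (0.664), HDAC2 (0.374) and MT-ND1 (0.291) among them. Another 17 kept their call under it with a log2 fold change moved by over 1.5 times: MKI67 and TOP2A fell further, to -0.4705 and -0.404, and MAP1LC3B (0.2162), ATP5F1B (0.177), MT-ND2 (0.3337), MT-ND3 (0.2153), RPS2 (0.2567), RPL5 (0.222), RPLP0 (0.1822), RPL7 (0.202), HSPH1 (0.1789), HSPE1 (0.2075), GCLM (0.2299), VIM (0.2465), MYOF (0.1705), NOP56 (0.2551) and TFRC (0.1538) were nearer 0. Moves of that size with the call kept also came in other settings. MCRS1 stood at -0.1678 after the correction for GC content and MT-ND4L at 0.2082 after that for exon length. GCLM stood at 0.2694 without WT replicate 2, and ELAVL3 at 3.379 without the library labelled WT replicate 1. With a library left out, 3 to 11 calls were lost. The other scalings, filters, tests and corrections ended fewer: 4 under the correction for GC content (KAT5 at 0.17, HDAC2 at 0.0508, TXN at 0.0934 and CRMP1 at 0.098), 3 under that for exon length (HAT1 at 0.067, KAT5 at 0.0793 and CRMP1 at 0.0526), 4 without a filter (KAT5 at 0.0667, KAT2B at 0.0519, CRMP1 at 0.0523 and ELAVL3 at 0.106), 3 with the replicate block (HAT1 at 0.0564, KAT5 at 0.0626 and KAT2B at 0.0634), and 1 each under upper quartile scaling (KAT2B at 0.0558), the filter of at least 50 counts (KAT2B at 0.0507) and DESeq2 (ELAVL3 at 0.0705); the cause was not tested. A threshold of 0.01 left 2143 higher and 2620 lower genes. Higher genes outnumbered lower ones after the corrections for GC content (3898 and 3684) and exon length (3953 and 3579); the cause was not tested. A minimum fold of 2 left 155 higher and 1005 lower, and a test against a fold of 1.2 left 884 and 1982, in each case because small changes no longer count. Camera with an estimated correlation called 0 lists; fry called 17. Under the correction for expression level, 3037 genes were higher and 3578 lower, and the direction turned for the NRF2 list (camera adjusted p = 0.527) and the list of mitochondrial DNA mRNAs (camera adjusted p = 0.862); the cause was not tested. KAT8 passed the threshold under 2 alternatives. Without a filter its log2 fold change was 0.61 with an edgeR adjusted p of 6.72e-16, in a fit of 37044 genes, and the cause was not tested. With the replicate number as a block it was 1.215 with an edgeR adjusted p of 0.000788. The numbers did not pair the libraries: same-numbered libraries had residual correlations of 0.006, -0.039 and -0.037, and under the block 3205 genes were higher and 3678 lower. With every library thinned to 50% of its counts, 75.8% of the calls under 1 CPM were kept against 96.8% of those over 64 CPM, and at 25% of the counts 53.7% against 92.6%, so depth limits weakly expressed genes most.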

Other observations

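Some genes of the stems IFT, CFAP and BBS were lower in R98W, while none of these stem groups passed the camera threshold. These groups and genes, in no fixed list, were chosen after their values were seen. Of 15 intraflagellar transport genes (symbols starting with IFT), 8 were lower in R98W and 0 higher, with a median log2 fold change of -0.28, and of 30 CFAP genes, named for cilia and flagella, 11 were lower and 0 higher and 19 were not called. The CFAP genes were weakly expressed, at a mean of 0.128 log2 CPM against 4.44 for IFT. Among all tested genes under 1 CPM, 687 were lower and 153 higher. The called CFAP genes ran from weak ones such as CFAP54, at 0.847 CPM in WT, to CFAP36, at 47.7 CPM. Of 8 BBS genes, whose products form the BBSome and its chaperones, 5 were lower and 0 higher. IFT172 fell from 19.1 ± 3.5 to 6.25 ± 0.58 CPM, IFT22 from 26.7 ± 2.2 to 13.3 ± 1.1 CPM, IFT57 from 29.8 ± 1.4 to 17.9 ± 0.16 CPM and BBS9 from 13.6 ± 1.8 to 6.08 ± 1.07 CPM (SD, n = 3). IFT172 overlaps KRTCAP3. IFT88, IFT20 and IFT122 had log2 fold changes of 0.03, 0.06 and -0.03, none past the threshold. Among 260 groups of genes that share a symbol stem, none of these 3 passed the camera threshold, with adjusted p of 0.068 for IFT, 0.0789 for CFAP and 0.171 for BBS. Without the library labelled WT replicate 1, which was tried after the data were seen, IFT stood at 0.00923, CFAP at 0.0541 and BBS at 0.0767, and after the correction for expression level they stood at 0.0531, 0.251 and 0.247. With an estimated correlation the adjusted p of each was 0.907.

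Of the 260 stem groups, 6 passed the camera threshold, and 0 did with an estimated correlation, where the smallest adjusted p was 0.907. Zinc finger genes with the stem ZNF were lower in 157 and higher in 31 of 421 cases, with a median log2 fold change of -0.19 (camera adjusted p = 8.98e-05, and adjusted p = 0.907 with an estimated correlation). The ZSCAN genes, which carry a SCAN domain beside zinc fingers, were lower in 10 and higher in 1 of 16 cases, with a median of -0.46 (camera adjusted p = 0.00515, and adjusted p = 0.907 with an estimated correlation). ZSCAN20 fell from 4.33 ± 0.66 to 1.92 ± 0.14 CPM and ZSCAN12 from 7.09 ± 0.83 to 4.34 ± 0.59 CPM, whereas ZSCAN31 had a log2 fold change of 0.31. After the correction for expression level, camera adjusted p was 0.0178 for ZNF and 0.0395 for ZSCAN, with medians of -0.121 and -0.358. The stems RPL, RPS, MCM and EIF were the other 4, with 43 of 49, 29 of 44 and 17 of 54 genes higher for RPL, RPS and EIF and 9 of 10 lower for MCM, and the EIF and RPS calls ended under that correction, at 0.959 and 0.205, while the RPL median went from 0.315 to 0.129 and the RPS median from 0.299 to 0.123. The EIF call also ended without the library labelled WT replicate 1, at 0.079.

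The tests on the low KAT8 library and on the histone genes, and the test on extra KAT8 mRNA, were chosen only after those results were seen, as were the corrections for GC content, exon length and expression level.

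The library labelled WT replicate 1 lacked the high KAT8 count of the other 5. Low depth is excluded, since its total was 94.7% of the mean of the other libraries. An exchange with an R98W library is argued against, since this library lay at a median of 0.793 on a scale from R98W (0) to the other WT libraries (1), over 1265 genes called at 2-fold or more without it. WT replicates 2 and 3, each over the genes called without that library, lay at 1.03 and 1.01, on a reference that includes the library labelled WT replicate 1. The R98W libraries, placed the same way from WT (0) to the other R98W libraries (1), lay at 0.864, 0.914 and 0.935. That the cells carried no extra KAT8 mRNA remains open, because its 12.2 CPM cannot be set against a library without overexpression here.

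Falls outweighed rises among changes of at least 2-fold, with 86.6% of them lower in R98W. Technical trends as the whole cause are argued against, since the share stayed at 83.8% after correction for GC content, 85.0% after correction for exon length and 74.5% after correction for expression level. It was at least 85.8% under the other scalings. Those moved the median log2 fold change of all tested genes only from -0.00465 to 0.00398 and -0.0179. They could hardly alter the share, so they do not decide on scaling. Copy number loss over long stretches is argued against, since no run of 51 neighbouring genes had a median log2 fold change under -0.3, the lowest being -0.27. That 0% of 410 such falls of at least 1 CPM lay in such runs follows from this and would hold for any genes. Losses over shorter stretches were not tested. One hypothesis is that extra wild-type KAT8 mRNA raised these genes. Yet the library labelled WT replicate 1, with little KAT8 mRNA, lay at a median of 0.814 on the same scale over the genes lower in R98W. WT replicates 2 and 3 lay at 1.05 and 1.02. Over the genes higher in R98W it lay at 0.613, against 0.79 and 0.73. The library labelled WT replicate 1 is part of the reference for WT replicates 2 and 3, so these gaps are not independent of it. R98W replicates 1 to 3, placed from WT, lay at 0.868, 0.924 and 0.927 over the lower genes and at 0.834, 0.848 and 0.953 over the higher. The test rests on 1 library whose history is unknown, so the hypothesis stays open. So does any effect of R98W itself, which the design cannot part from other differences between the cell populations.

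Histone mRNAs of the replication-dependent class were higher in R98W although the S phase list had a median log2 fold change of -0.339. More cells in S phase would raise that list only if its genes kept their level per cell. Transcript levels do not count cells in S phase, and the share of such cells was not measured, so the list does not decide this. More RNA without a poly(A) tail in the R98W libraries may account for the higher histone counts, but the RNAs tested do not decide this. Of 22 other RNAs without a regular tail 7 were tested, with 3 higher and 0 lower. Their median log2 fold change was 0.743, which is that of MT-RNR2. The others called were MT-RNR1, at 1.02, and SCARNA7, at 1.07 and under 1 CPM. SNORD17 (0.0189, edgeR adjusted p = 0.942) and RN7SL2 (-0.393, edgeR adjusted p = 0.617) were not called. Neither were SNORD3A (0.851, edgeR adjusted p = 0.0602) and SNORA73B (0.446, edgeR adjusted p = 0.44), both under 1 CPM. By biotype, 10 of 22 mitochondrial tRNA genes were higher and 0 lower, with a median of 0.561. Of 53 snoRNA genes, 1 was higher and 0 lower, with a median of 0.388. Of the 3 called RNAs, MT-RNR1 and MT-RNR2 are mitochondrial, as are the tRNA genes. The mRNAs of mitochondrial DNA were also higher in 5 of 13 cases and lower in 0, with a median of 0.187. These RNAs therefore do not separate RNA selection from a rise of mitochondrial RNA. The nuclear RNAs tested above 1 CPM, SNORD17 and RN7SL2, were not higher past the threshold. A difference in RNA selection and a difference in histone mRNA cannot be told apart either, since both would raise the histone counts.

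Other splits of the 6 libraries number 10 with the real one, too few for a share under 0.05. The real split gave 3364 higher genes in 1 of 10 splits and 3839 lower genes in 1 of 10, and the highest other split gave 0 of either. Every other split mixes WT and R98W libraries, so the difference between WT and R98W enters the spread within its groups. The common dispersion was 0.043 to 0.05 in those splits against 0.01 in the real one. Few gene calls there were fixed in advance, so these splits do not measure chance. For gene lists the real split gave 13 called lists. The highest other split, which set the library labelled WT replicate 1 with R98W replicates 2 and 3, also gave 13, so 2 of 10 splits gave as many. The mixed splits still carry part of the difference between WT and R98W, so the list counts do not measure chance either.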
